A study of Mus musculus with 4 samples.

How the data were processed

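Gene expression was measured on Affymetrix MOE430 2.0 arrays, oligonucleotide arrays on which each transcript is read by 1 or more probe sets of short probes. Each of the 4 arrays held total RNA of mouse prefrontal cortex pooled from 5 animals, per the labels. There were 2 pools of mice exposed to repeated social threat and 2 pools of control mice. Per the labels' protocols, total RNA was extracted with a Qiagen RNEasy kit, and biotin-labelled target was made by the standard Affymetrix procedure.

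The values deposited by the authors were log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA, a method that, as usually run, corrects background, brings the arrays to a common distribution and summarises each probe set. The version, its settings, the chip definition and any filter are not given in the sources used here. The scale was checked on the values, which ran from 2.51 to 14.37 with array medians between 5.53 and 5.58. Where arrays are brought to a common distribution, a change of most transcripts in 1 direction would not be visible. Scanner files and detection calls were not used here, so no probe set was called present or absent. As a guide to background, the 27 Bacillus control probe sets, which match no mouse transcript, ranged from 3.01 to 4.25 over the 4 arrays. The means of 29.8% of all probe sets lay at or below that upper value.

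The table held 45101 probe sets, of which 64 were control probe sets and were left out of all tests, leaving 45037. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 were unnamed here. The Entrez ID of 34741 of the 34945 was found in a table of mouse genes (GRCm38.p6), and no symbol needed an update. Only probe sets with 1 symbol were named, which covered 18193 genes. No genome build is named for the array values, so no coordinates are given.

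Threat was compared with control on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, 2-sided, Benjamini-Hochberg adjustment over all 45037 probe sets). The fit had 2 residual degrees of freedom, to which limma adds information from all probe sets. The median standard error of a log2 difference was 0.108. Because 2 pools a side leave little power, a rule of size was also applied: a mean difference of at least 1.5-fold with both threat pools above, or both below, both control pools ("separate pools"). Chance puts the pools of 33.3% of unchanged probe sets apart, 16.7% in each direction. An exact permutation test of 2 against 2 cannot go below a 2-sided p of 0.333, so none was used. The number of arrays limits the precision. Each pool averages 5 mice, so the spread between pools is not the spread between animals, and labels do not say whether the mice of different pools came from different cages or days.

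Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists held pathways, cell type markers and markers of other brain regions. Of 787 genes on the lists, 717 were measured under a single symbol, each by its probe set with the highest mean. The lists were tested with limma's camera, which asks whether the genes of a list differ on balance in 1 direction from the other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Fry asks whether the genes of a list change on balance, without setting them against the other genes. Neither alternative called any list, so every list call below holds only with the preset correlation. Both alternatives rest on the 2 residual degrees of freedom, which leaves them little power. Their lack of calls therefore cannot decide for or against a list. Named genes were, per direction, the 12 genes with the largest difference among probe sets with an adjusted p under 0.05 and separate pools. Where fewer passed, the 12 were filled by size from probe sets with separate pools, an unadjusted p under 0.05 and a mean above 5.56, the median of all probe sets ("bright" below). The up to 4 members of each list with the largest difference were named too. Fewer are given below for the oxidative phosphorylation, ribosomal, cell cycle, matrix and Y-linked lists. A p adjusted over the list alone covers the genes of that list and does not correct for the other lists. This adjustment was not among the tests fixed beforehand. Every gene that passed it had an adjusted p of at least 0.278 over all probe sets.

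Other alternatives were the pool number as a replicate block, cyclic loess, median centring and an intensity trend. Also run were bright probe sets alone, probe sets not ending in _x_at or _s_at, other thresholds and the mean of a gene's probe sets. Each pool was left out in turn. After the data were seen, list members were also counted without those whose 4 pools all lay at or below the highest Bacillus control value, and a named member with only its threat pools there was given as a bound. Both groups carry pool numbers 1 and 2. Nothing in the labels says that a number marks a shared day or cage, so the main comparison had no block. The scripts were tested on simulated data for the threat and control comparison with 45037 probe sets. Of 66 probe sets changed 4-fold, 89.4% passed the adjusted p and 100% passed the rule of size. Of 67 changed 2-fold, 34.3% passed the adjusted p and 100% the rule of size, and of 67 changed 1.5-fold, 1.5% and 44.8%. Among 44837 simulated unchanged probe sets, 3 passed the adjusted p and 321 passed the rule of size, 159 of them lower. The simulated noise was independent between probe sets and arrays. Noise shared by many probe sets of a pool was not simulated, so these shares need not hold for the real arrays.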

Results

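Prefrontal cortex of mice exposed to repeated social threat was compared with that of control mice, to ask which transcripts differ between the 2 environments. Each group was represented by 2 pools of RNA from 5 mice. The arrays were close to each other, with correlations across probe sets between 0.9942 and 0.9961. Between the 2 control pools, 907 probe sets differed by at least 1.5-fold, and between the 2 threat pools 734 did. A control and a threat pool differed at this size in 742 to 1531 probe sets, the lowest number being that of control pool 2 and threat pool 2. The 3′ to 5′ log2 signal ratios of the Gapdh and Actb control probe sets, a sign of RNA integrity, were higher by 0.038 and 0.051 in the threat pools. Those of Pcx and Tfrc differed by -0.105 and 0.012. Each of these differences was smaller than that between the 2 threat pools.

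All 25 measured genes of the myelin list lay lower in the threat pools, with a median log2 difference of -0.68, while no single gene passed the test over all probe sets. No probe set passed an adjusted p of 0.05 in limma's test, in which the smallest adjusted p was 0.278, against 0.0663 when the same 4 arrays were split by pool number (control 1 and threat 1 against control 2 and threat 2). At an unadjusted p under 0.05 there were 4774 probe sets, 10.6% of those tested, of which 2193 were higher and 2581 lower in threat. That share was 5.4% in the split by pool number and 1.1% in the remaining split. The rule of size was met by 374 probe sets, of which 324 (86.6%) were lower and 50 higher in threat. The pools of 43.2% of all probe sets were separate, against the 33.3% that chance gives, 33.0% in the split by pool number and 21.5% in the remaining split. Apart from ties, a probe set is separate in exactly 1 of the 3 splits, so these shares are not independent of each other. Between threat and control, 23.9% of all probe sets were separate with threat higher and 19.4% with threat lower. The median log2 difference of bright probe sets was 0.058. The split by pool number gave 454 probe sets past the rule of size, with 58 higher and 396 lower in number 1. The remaining split gave 19. In simulated data with noise independent between probe sets, 321 of 44837 unchanged probe sets met the rule. Noise shared between probe sets was not simulated, so 321 is not the count to be set against 374. The count of 374 came to 736 without control pool 1 (146 higher and 590 lower), 782 without control pool 2 (311 and 471), 673 without threat pool 1 (321 and 352) and 818 without threat pool 2 (109 and 709), where fewer pools have to be separate. The share of lower probe sets was thus 60.2% without control pool 2 and 52.3% without threat pool 1.

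The 12 genes named for lower values in threat included 3 of the myelin list. By its probe set with the largest difference, Mobp, a structural protein of central myelin, measured 10.996 ± 0.454 in the control and 9.419 ± 0.294 in the threat pools (log2, SD, n = 2 each), a log2 difference of -1.58 ± 0.25 (SE) or 2.98-fold. Cldn11, the tight junction protein of the myelin sheath, was 2.46-fold lower and Mal, a proteolipid of myelin, 2.23-fold lower. Acta2, smooth muscle actin, was 3.56-fold lower, the tropomyosin Tpm2 2.82-fold, the calponin relative Tagln 2.72-fold and the smooth muscle myosin Myh11 2.35-fold. The size of these 4 differences depended on the control pools: without control pool 2 and without control pool 1, the log2 difference was -1.19 and -2.48 for Acta2, -0.72 and -2.28 for Tpm2, -0.81 and -2.07 for Tagln and -0.72 and -1.75 for Myh11. The log2 difference of Cytl1 was likewise -0.60 and -1.82. The largest difference among these 12 genes was that of 1 probe set of Ywhaz, an abundant 14-3-3 protein, at -2.04 ± 0.22 (4.13-fold). The 6 other bright probe sets of Ywhaz averaged -0.17. Cd24a was 2.47-fold lower, Abtb2 2.39-fold, Cytl1 2.31-fold and Sesn1, a stress-responsive regulator of growth signalling, 2.27-fold. The other bright probe sets averaged -0.51 for Cd24a, -0.12 for Abtb2 and -0.24 for Sesn1. The adjusted p of these 12 lay between 0.28 and 0.45 in limma's test.

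Of the 12 genes named for higher values in threat, 11 differed by 1.80-fold or less. Cryl1, a crystallin-related dehydrogenase, measured 7.19 ± 0.80 in control and 8.62 ± 0.17 in threat, a log2 difference of 1.43 ± 0.36 (SE) or 2.70-fold, while its 3 other bright probe sets averaged 0.12. Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, was 1.80-fold higher, Hltf 1.75-fold, Dennd6b 1.69-fold and Ptprn2, a protein of dense-core vesicles, 1.66-fold. Apc2 was 1.64-fold higher, Slc16a13 1.62-fold, F8a 1.62-fold, the growth factor Vegfd 1.61-fold, Ankrd24 1.61-fold, the receptor for thyrotropin-releasing hormone Trhr 1.60-fold and the ubiquitin ligase Cbl 1.59-fold. The other bright probe sets of these genes averaged 0.21 for Pik3cd, 0.07 for Hltf, 0.25 for Dennd6b, 0.09 for Ptprn2, 0.15 for Apc2, 0.10 for F8a, 0.41 for Vegfd, 0.51 for Ankrd24, 0.36 for Trhr and 0.18 for Cbl. The adjusted p of the 12 in limma's test lay between 0.34 and 0.44. The log2 difference of Cryl1 was 0.87 without control pool 1, that of Vegfd 0.39 without control pool 1, that of Cbl 0.41 without control pool 2 and that of Ptprn2 0.49 without threat pool 2.

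Genes of myelinating oligodendrocytes were lower in the threat pools as a group. All 25 measured members of the list lay below 0, with a median log2 difference of -0.68 (quartiles -0.92 and -0.37), and 20 had separate pools. None passed an adjusted p of 0.05 over all probe sets, and 15 were lower at an adjusted p under 0.05 adjusted over the list alone. By the list's own probe set, Mobp was -1.31 ± 0.23 (SE), Cldn11 -1.30 ± 0.15, Mal -1.16 ± 0.18 and Ugt8a, the enzyme that makes the galactolipid of myelin, -1.13 ± 0.22. The list was called lower in camera with an adjusted p of 5.5e-17. Its adjusted p was 0.70 with an estimated correlation. Of 8 bright probe sets of Mbp, myelin basic protein, 6 lay below 0 and 2 at 0.22. Leaving out 1 pool moved the median between -0.50 (without control pool 1) and -0.86 (without control pool 2), and camera called the list each time. Its median was 0.10 in the split by pool number (adjusted p = 0.33) and 0.29 in the remaining split, where camera also called it (adjusted p = 1.5e-06). Markers of oligodendrocyte precursors, the cells that give rise to oligodendrocytes, had a median of -0.10 over 15 genes, and the list was not called (adjusted p = 0.14) except without threat pool 2 (adjusted p = 0.0093). Its members with the largest differences were Enpp6 at -0.44, Sox10 at -0.25, Vcan at 0.22 and Bmp4 at -0.21. Bmp4 turned to 0.23 without control pool 2 and 0.33 without threat pool 1, and Sox10 was at -0.10 without control pool 1.

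**Figure D1:**
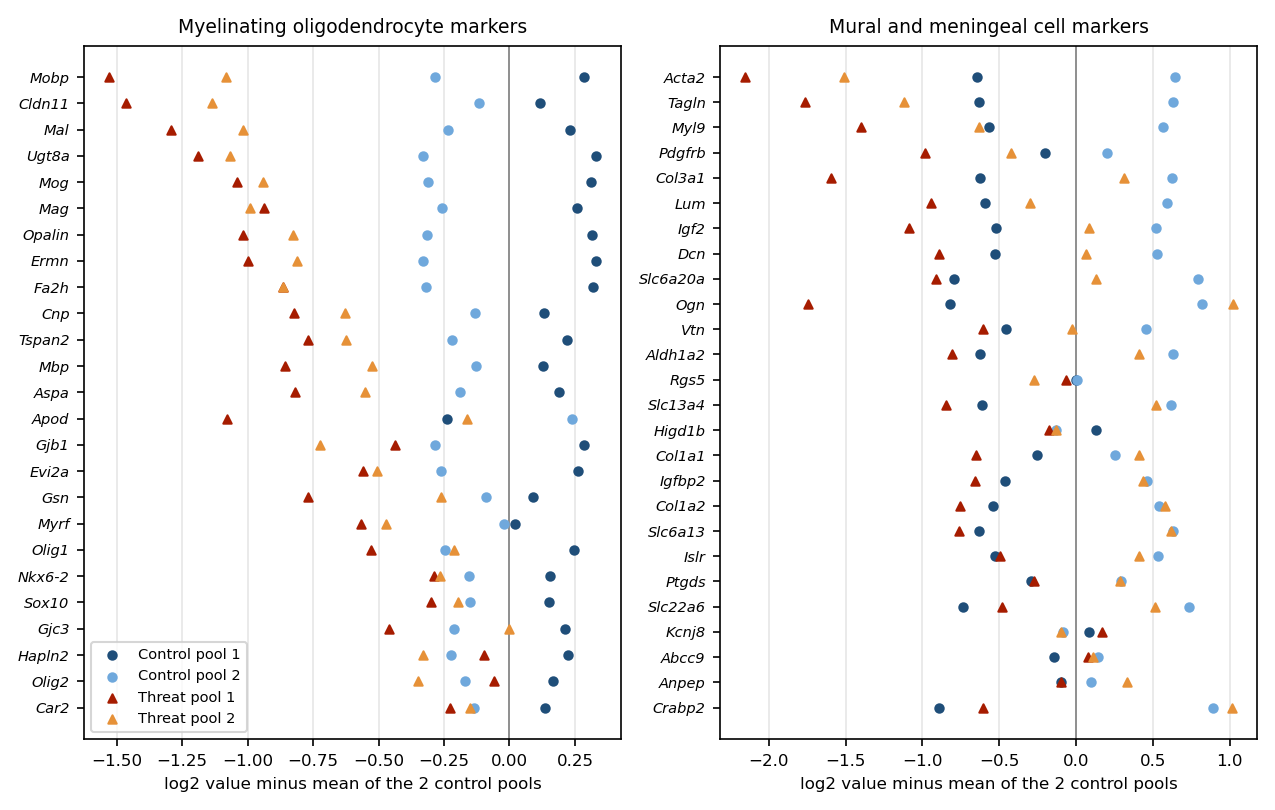
Log2 values of each pool minus the mean of the 2 control pools (x axis) for each measured gene (y axis) of the myelinating oligodendrocyte list (left) and the mural and meningeal list (right), with control pools as circles and threat pools as triangles. In the left panel the threat pools lie below both control pools for 20 of 25 genes, while in the right panel they do so for 6 of 26.

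The lists of blood vessel, brain covering and ventricle lining markers had medians below 0 in threat, with wide spread between pools for several members. The mural and meningeal list (pericytes, smooth muscle, fibroblasts of the meninges) had a median of -0.17 over 26 genes, with 6 lower and none higher with separate pools, led by Acta2 (-1.83 ± 0.44), Tagln (-1.44 ± 0.44), Myl9 (-1.01 ± 0.42) and Pdgfrb (-0.70 ± 0.23). Camera called it lower (adjusted p = 0.013; adjusted p = 0.72 with an estimated correlation), but its direction turned without control pool 2 (adjusted p = 0.83) and without threat pool 1 (adjusted p = 0.81). In the split by pool number the same list had a median of -0.98, farther from 0 than between threat and control, and was called (adjusted p = 1.1e-30). The endothelial list had a median of -0.27 over 23 genes, with Vwf, the clotting factor carrier of endothelium, at -1.08 ± 0.39, Pecam1 at -0.63, Pltp at -0.56 and Fn1 at -0.46. It was called lower (adjusted p = 0.00039; adjusted p = 0.72 with an estimated correlation), and the call was lost without control pool 2 (adjusted p = 0.21) and threat pool 1 (adjusted p = 0.30). Its median in the split by pool number was -0.28, where it was also called (adjusted p = 1.7e-11). Without control pool 2, Acta2 was at -1.19, Tagln at -0.81, Myl9 at -0.45, Pecam1 at -0.37 and Fn1 at 0.16. Without threat pool 1, Vwf was at -0.59, Pdgfrb at -0.42, Pltp at -0.33 and Fn1 at 0.49. No member of either list passed when adjusted over the list alone.

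The choroid plexus and ependyma list had a median of -0.29 over 20 genes, and 10 had separate pools, each lower in threat. In 4 of the 20 all pools lay at or below the highest Bacillus control value, and 9 of the 16 others had separate pools, with a median of -0.32. Ttr, the transthyretin made by choroid plexus, measured 7.77 ± 1.82 in control and 6.17 ± 0.02 in threat, a difference of -1.60 ± 0.78, with 9.05 and 6.48 in the control pools. Both threat pools of Tmem212 were under the highest Bacillus control value, which puts it at least 1.81-fold lower by the mean of the control pools, and Ccdc153 was at -0.88 and Clic6 at -0.56. Without control pool 1, Ttr was at -0.32, Ccdc153 at -0.30 and Clic6 at -0.36. The bound for Tmem212 also depended on that pool, without which its log2 difference was -0.74 in place of -1.17. With all pools, no member passed when adjusted over the list alone. Camera called the list lower (adjusted p = 0.00029; adjusted p = 0.70 with an estimated correlation), also without each pool in turn. The blood cell list was called lower (median -0.15 over 12 genes, adjusted p = 0.0031; adjusted p = 0.70 with an estimated correlation), and not without threat pool 2 (adjusted p = 0.094). The calgranulins S100a8 (-1.02) and S100a9 (-0.89) of neutrophils and Alas2 (-0.61), the erythroid enzyme of haem synthesis, led it, with Bpgm at -0.27. S100a8 was at -0.45 and S100a9 at -0.30 without control pool 1. Alas2 alone passed when adjusted over the list alone (adjusted p = 0.032). In the split by pool number the blood list had a median of 0.20 (adjusted p = 0.032).

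Immune lists had medians below 0 in threat. Of 34 genes on the list of inflammatory cytokines and NF-kB targets, 26 lay below 0 and 8 above, 15 had separate pools with threat lower and 3 with threat higher, and the median was -0.12. These counts include 6 genes with all pools at or below the highest Bacillus control value. Of the 28 others, 23 lay below 0, 13 had separate pools with threat lower and 2 with threat higher, and the median was -0.14. Lcn2, the iron-sequestering lipocalin of acute inflammation, measured 6.47 ± 0.44 in the control pools and 4.22 and 4.40 in the threat pools, near the highest Bacillus control value of 4.25, so that the size of its difference (-2.16) is uncertain. It was the single member that passed when adjusted over the list alone (adjusted p = 0.0031; 0.32 over all probe sets). Icam1 (-0.46), Nfkb2 (-0.46) and the chemokine Ccl4 (-0.41) followed, with Icam1, near the Bacillus controls in threat pool 1, at -0.14 without that pool. The list was called lower (adjusted p = 0.00032; adjusted p = 0.70 with an estimated correlation) and also without each pool in turn.

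The type I interferon list had a median of -0.11 over 33 genes, with Ifitm3 at -0.58, Ifit1 at -0.45 and Rsad2 at -0.40, and was called lower (adjusted p = 0.0099; adjusted p = 0.72 with an estimated correlation). Eif2ak2 was lower in both threat pools, but these measured 4.25 and 4.36, near the highest Bacillus control value, so that the size of its difference (-0.64) is uncertain. The call was lost without control pool 2 (adjusted p = 0.87) and threat pool 1 (adjusted p = 0.99). The antigen presentation list had a median of -0.19 over 20 genes, led by H2-D1 (-0.39), H2-Ab1 (-0.38), Cd74 (-0.34) and Psmb8 (-0.34). It was called with the same adjusted p of 0.0099 (adjusted p = 0.72 with an estimated correlation) and lost without control pool 2 (adjusted p = 0.16) and threat pool 1 (adjusted p = 0.99). Without threat pool 1, Ifitm3 was at -0.01, Ifit1 at 0.05, Rsad2 at -0.07, H2-D1 at -0.15, H2-Ab1 at 0.17, Cd74 at 0.39 and Psmb8 at -0.12, and without control pool 2, Ifitm3 was at -0.16, Ifit1 at 0.26, H2-Ab1 at -0.17 and Cd74 at 0.03. No interferon or antigen presentation gene passed when adjusted over the list alone. With all pools, camera's call of the antigen presentation list was also lost without the probe sets ending in _x_at or _s_at (adjusted p = 0.053). Both lists were also called in the split by pool number, with medians of -0.21 (adjusted p = 1.4e-11) and -0.23 (adjusted p = 8.9e-06), and the antigen presentation list also in the remaining split (adjusted p = 0.024). The neurotrophin and growth factor list was called lower (median -0.11 over 26 genes, adjusted p = 0.004; adjusted p = 0.70 with an estimated correlation), and lost without control pool 2 (adjusted p = 0.15) and threat pool 1 (adjusted p = 0.18). It was also called in the split by pool number (adjusted p = 0.0022). In all pools, 4 of its genes, 3 interferon, 2 blood cell and 1 antigen presentation gene lay at or below the highest Bacillus control value. Igf2 was at -0.50, Fgfr3 at -0.48, Vegfa at -0.47 and Tgfa at -0.40, and Igf2 turned to 0.02 without control pool 2 and 0.09 without threat pool 1.

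The microglia and macrophage list had a median of -0.18 over 26 genes, and 14 had separate pools, each lower in threat. The lysozyme Lyz2 was at -0.58, Sall1 at -0.42, Fcgr3 at -0.41 and the complement gene C1qa at -0.33. It was called lower (adjusted p = 0.00029; adjusted p = 0.70 with an estimated correlation), and not without threat pool 1 (adjusted p = 0.16). It was also called in the split by pool number (adjusted p = 0.049) and in the remaining split (adjusted p = 0.00097). The astrocyte list had a median of -0.10 over 22 genes, with Gfap, the astrocyte intermediate filament, at -0.59 ± 0.13, Fgfr3 at -0.48, Gjb6 at -0.36 and Gja1 at -0.36. All 3 bright probe sets of Gfap had separate pools, with a mean of -0.64. Without threat pool 1, Lyz2 was at -0.22 and Gjb6 at 0.03, and without control pool 1, Fcgr3 was at -0.22 and C1qa at -0.15. The astrocyte list was called lower (adjusted p = 0.0031; adjusted p = 0.72 with an estimated correlation), and not without threat pool 1 (adjusted p = 0.52), and it was also called in the remaining split (adjusted p = 0.00095). No member of either list passed when adjusted over the list alone.

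Neuronal lists were not called. Excitatory cortical neuron markers had a median of 0.07 over 25 genes, a mean of 0.03 and an adjusted p of 0.99, with camera's direction opposite to both. Ccn2, a marker of the deepest cortical layer, was lower at -0.72 ± 0.12 when adjusted over the list alone (adjusted p = 0.026), while Tbr1 (-0.53), Neurod6 (-0.39) and Otof (0.56; 0.21 without control pool 1) did not pass. Interneuron markers had a median of -0.06 (adjusted p = 0.18), with Adarb2 at 0.54, Maf at -0.44, the GABA-synthesising enzyme Gad1 at -0.42 and Crh at -0.42. Adarb2 was at 0.31 without control pool 1, and Maf at -0.14 without control pool 2 and -0.17 without threat pool 1. GABA receptor and transporter genes had a median of 0.01 and, with the direction of the test, a mean of -0.02 (adjusted p = 0.56), with Slc6a11 at 0.37, Gabra2 at -0.35 and Gabra3 at 0.35 after Gad1, and without control pool 2 Gabra2 was at -0.15 and Slc6a11 turned to -0.12. Glutamate receptor genes had a median of 0.13 (adjusted p = 0.12), with Grik4 at 0.46, Grm8 at 0.41 (0.23 without threat pool 1), Grik2 at 0.31 (0.16 without control pool 1) and Gria3 at -0.28, and were called higher without control pool 2 (adjusted p = 0.028). Synaptic genes had a median of 0.06 (adjusted p = 0.64), with Shank1 at -0.28, Rab3a at -0.21, Pclo at 0.21 and Dlg3 at 0.20 (0.07 and 0.12 without control pool 1), and were called higher without control pool 2 (adjusted p = 0.027). The list of stress hormone, monoamine and neuropeptide signalling genes had 23 of 47 members below 0 (adjusted p = 0.67), with the stress peptide Crh (-0.42), Penk (-0.42), Adcyap1 (0.35) and Cnr1 (-0.34) at its ends. Without control pool 1, Penk was at -0.14 and Adcyap1 at 0.20, and without control pool 2, Cnr1 was at -0.14.

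None of the lists for other brain regions (striatal, thalamic and septal, olfactory and piriform) was called in the main test. Striatal markers had a median of -0.02 (adjusted p = 0.16), and Pde10a, a phosphodiesterase of striatal projection neurons, was lower at -0.76 ± 0.09 when adjusted over the list alone (adjusted p = 0.0044), with Isl1 at -0.61, Penk at -0.42 and Six3 at -0.39, which were at -0.11, -0.14 and -0.24 without control pool 1. Thalamic and septal markers had a median of -0.05 (adjusted p = 0.20), with Prkcd at -0.90, Plekhg1 at -0.46, Zic2 at -0.41 and Zic1 at -0.89, of which Zic1 alone passed when adjusted over the list alone (adjusted p = 0.047). Prkcd was at -0.31 without control pool 1, and without threat pool 1 Plekhg1 was at -0.09 and Zic2 turned to 0.26. Olfactory and piriform markers had a median of -0.13 (adjusted p = 0.074), with Lbhd2 at -0.74, Cdhr1 at 0.50, Sp8 at -0.49 and Omp at -0.44. Without control pool 1, Lbhd2 was at -0.48, Sp8 at -0.12 and Omp at -0.21, and without threat pool 2, Cdhr1 was at 0.24. The threat pools of Isl1 and Sp8 were near the highest Bacillus control value, so that the size of their differences is uncertain. Without control pool 2 the striatal (adjusted p = 0.0015), olfactory (adjusted p = 0.011) and thalamic (adjusted p = 0.031) lists were called lower.

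Stress-related and activity-dependent genes gave mixed values. The glucocorticoid-responsive list was called lower (median -0.06 over 29 genes, adjusted p = 0.0099; adjusted p = 0.70 with an estimated correlation), but its leading members were Lcn2, whose threat pools were near background, Sult1a1 (-0.74), Tgm2 (-0.70) and Litaf (-0.43). Without threat pool 1, Sult1a1 was at -0.33 and Tgm2 at -0.41. With all pools, Lcn2 alone passed when adjusted over the list alone (adjusted p = 0.0026). The hormone-induced genes Fkbp5 (-0.03), Sgk1 (-0.26), Tsc22d3 (-0.24) and Klf9 (0.07), chosen after their values were seen, did not pass. The call was lost without control pool 2 (adjusted p = 0.20) and threat pool 1 (adjusted p = 0.18). The heat shock and unfolded protein list was called lower (median -0.08 over 30 genes, adjusted p = 0.0084; adjusted p = 0.70 with an estimated correlation) and lost without threat pool 1 (adjusted p = 0.36). Cryab, a small heat shock protein abundant in oligodendrocytes, was at -0.78 (adjusted p = 0.047 adjusted over the list alone), Hspa1b at -0.55, Hspb1 at -0.48 and Dnajb9 at -0.38. Hspa1b was at -0.26 without threat pool 1, where Hspb1 was at -0.18, and Hspb1 turned to 0.05 without control pool 2.

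Clock genes made the single list called higher in threat (median 0.12 over 19 genes, adjusted p = 0.043; adjusted p = 0.72 with an estimated correlation). Per3 was at 0.58 ± 0.15, Nfil3 at 0.31, Hlf at 0.25 and Per2 at 0.23, and none passed when adjusted over the list alone. The list was called at a smaller adjusted p in the split by pool number (0.0038) and in the remaining split (0.0016). Nfil3 was at 0.08 without threat pool 2 and Per2 at 0.08 without control pool 1. Camera no longer called the clock list without threat pool 1 or threat pool 2, and camera's direction turned without control pool 1. The list's own median stayed between 0.023 and 0.258 without 1 pool. With all pools, the call was also lost with cyclic loess, with bright probe sets alone and with the mean of a gene's probe sets. It was lost too without the probe sets ending in _x_at or _s_at. Immediate-early genes, which neurons induce within minutes of activity, were not called (median 0.03 and mean 0.04 over 36 genes with camera's direction opposite, adjusted p = 0.99), with Egr3 at -0.48, Fosb at 0.46, Npas4 at 0.39 and Gadd45g at 0.38, of which Npas4 turned to -0.31 and Fosb was at 0.05 and Gadd45g at 0.07 without control pool 1, and Egr3 at -0.29 without control pool 2. They were called lower without control pool 1 (adjusted p = 3.7e-07) and higher without control pool 2 (adjusted p = 1.4e-06). In the split by pool number their median was -0.40 with an adjusted p of 1.9e-20, and they were also called in the remaining split (adjusted p = 1.4e-05).

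The lists of oxidative phosphorylation (median 0.02, adjusted p = 0.82), ribosomal proteins (median -0.04, adjusted p = 0.078) and cell cycle genes (median -0.10, adjusted p = 0.16) were not called. Nor were the lists of extracellular matrix and perineuronal nets (median -0.12, adjusted p = 0.084) and Y-linked genes with Xist (median 0.08, adjusted p = 0.23). With the replicate block, camera called the matrix list lower (adjusted p = 0.049). Other processing also gained calls for the matrix and ribosomal lists. Without control pool 2 the ribosomal (adjusted p = 0.017) and cell cycle (adjusted p = 1.7e-05) lists were called lower, and the matrix list was called lower without control pool 1 (adjusted p = 0.0043) or threat pool 2 (adjusted p = 0.0010). Their leading members were Cox7c (0.28) and Ndufs1 (0.16), Rpl37 (-0.46) and Rpl14 (0.20), Bub1b (-0.38) and Mki67 (-0.35), Timp4 (-0.47) and Fn1 (-0.46), and Eif2s3y (0.20) and Uty (0.20). Cox7c was at 0.12 and Timp4 at -0.30 without threat pool 1, and Bub1b at -0.22 without threat pool 2. Mki67 turned to 0.13 without control pool 1, Fn1 to 0.16 without control pool 2 and 0.49 without threat pool 1, and Eif2s3y to -0.05 without threat pool 1. Xist, expressed from the inactive X chromosome of female cells, measured 5.00 ± 0.02 in the control and 5.08 ± 0.04 in the threat pools.

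With the preset correlation, camera called 14 of the 30 lists between threat and control, 13 lower and 1 higher in threat. Some lists share genes, such as Lcn2 on the glucocorticoid-responsive and inflammatory lists and Fgfr3 on the astrocyte and neurotrophin lists. The calls are thus not independent of each other. The split by pool number also called 14 lists and the remaining split 10, of which 8 and 5 were among the 14, so that a call by this test did not set threat against control apart from other splits of the arrays. The glucocorticoid-responsive, inflammatory, choroid plexus and heat shock lists were called in neither other split, but some came close. Camera's adjusted p for these lists, in this order, was 0.0695, 0.0626, 0.855 and 0.0833 in the split by pool number. In the remaining split it was 0.946, 0.976, 0.0524 and 0.0594. The glucocorticoid-responsive median was -0.088 in the split by pool number and -0.061 between threat and control. Of lists not called for threat, the split by pool number called the immediate-early, precursor, striatal, oxidative phosphorylation, cell cycle and matrix lists. The remaining split called the immediate-early, olfactory, thalamic, synaptic and cell cycle lists. With an estimated correlation and with fry, 0 of 30 lists were called between threat and control. Camera's adjusted p then ran from 0.703 to 0.993 and fry's was at least 0.658. With 2 residual degrees of freedom, both tests had little power. At an unadjusted p under 0.05, camera with an estimated correlation gave 1 list and fry 2. Fry's unadjusted p was under 0.05 for the glucocorticoid-responsive list (0.049) and the inflammatory list (0.022). The count of 14 fell to 4 without threat pool 1.

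**Figure D2:**
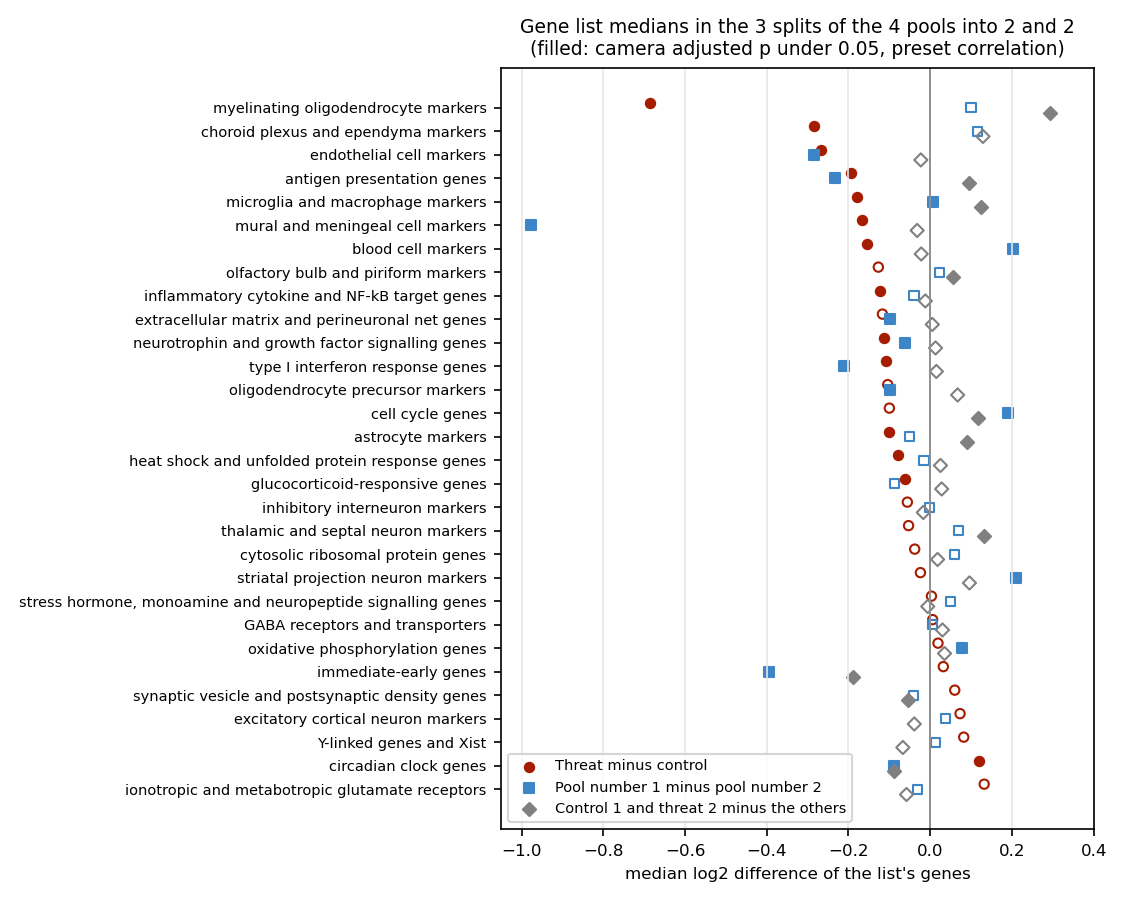
Median log2 difference of the genes of each of 30 lists (x axis; lists on the y axis) between threat and control (red circles), pool number 1 and 2 (blue squares) and the remaining split (grey diamonds), with filled symbols for lists called by camera with the preset correlation. The myelin list lies at -0.68 between threat and control and the mural and meningeal list at -0.98 between the pool numbers.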

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

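All tests of explanations in this part were chosen after the results were seen. Outlying samples within a group were not searched for, since each group held 2 pools. A signal outside the main measurement stood out in 18S ribosomal RNA control probe sets, which no comparison used. The 5′ and middle ones read higher in threat pool 2 than in the other pools. The 5′ probe set measured 12.92 there against at most 12.05 in the control pools and 11.82 in threat pool 1. The middle probe set measured 10.58 against at most 9.30 and 9.19. The 3′ probe set did not stand out, with 10.40 in threat pool 2, 10.31 in threat pool 1 and at most 10.10 in the control pools.

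Myelin genes were lower in the threat pools. In 10 of the 25 genes, other bright probe sets than the list's own could be read. Their mean lay below 0 in 100% of these genes (exact 95% interval 69.2 to 100). The interval takes the genes as independent and is too narrow, since camera estimated a correlation of 0.71 among the list's genes. Of the 22 probe sets, 20 lay below 0. This argues against a signal of single probe sets for these 10 genes and leaves the other genes untested. A smaller share of mature oligodendrocytes or white matter in the threat tissue and a lower expression within these cells both remain open and cannot be told apart. Both predict the gap of -0.58 between the myelin median and the lowest median of the precursor and neuron lists, and dissection and group coincide here. Of the 3 splits of the 4 arrays, 1 gave a median as far from 0 as the real one (0.685 in size, highest of the others 0.292), and 3 splits are too few for a share under 0.05.

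There were 324 probe sets at least 1.5-fold lower in threat. In 136 of the 204 named genes with such a bright probe set, another bright one that did not itself pass could be read. The median was -0.70 for the selected and -0.036 for the other probe sets (bootstrap 95% interval -0.087 to -0.016). Leaving out probe sets that passed draws the median of the others toward 0. It also drops genes whose bright probe sets all passed. The median of the others was -0.054 for probe sets with the suffix _a_at, _s_at or _x_at and -0.156 for plain ones. Probe sets chosen for their size overstate it, but in the split by pool number, with the same exclusion, the others followed (-0.324 for -0.698). That split had such others in 73 of 230 genes, so the comparison is not between like sets of genes. The median of -0.036 argues against a fall of the whole mRNA as the general explanation in these 136 genes. It leaves the dropped genes untested. However, 22 genes were lower with separate pools in all of at least 2 bright probe sets, with a mean of at least 1.5-fold. Probe sets ending in _x_at, whose probes share sequence with other transcripts, made 22.5% of the selected bright ones against 6.6% of all bright ones (Fisher's exact test, 2-sided, p = 5.5e-18 over probe sets, which are not independent) and 7.2% in the split by pool number, which is consistent with shared sequence as 1 source, while isoforms were not tested. Independent noise would make about as many higher as lower, against 86.6% lower, but the share was 52.3% without threat pool 1 and 60.2% without control pool 2, so that noise shared by the probe sets of 1 pool stays open, and the 3 splits (374 in the real one, 454 in the highest of the others, 2 of 3 as large) are too few for a share under 0.05.

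Differences followed the pool number in both groups. All 18 probe sets of hybridisation spike-ins were higher in number 1 than in number 2 in both groups. The medians were 0.21 in control and 0.20 in threat, as a hybridisation step shared by pools of 1 number would give. However, these probe sets read the same few spiked transcripts (bioB, bioC, bioD and cre) and are not independent of each other. With 1 pair of pools in each group, a shared sign can also arise by chance. The cre probe sets also read lower in both threat pools than in both control pools (for example 13.29 and 13.17 against 13.39 and 13.34). The same held for a bioD probe set, while the other bioD probe sets and those of bioB and bioC overlapped. A hybridisation difference between the groups was not tested. Mural and meningeal markers had a median of -0.976 between the numbers, against 0.028 for all genes, as more meninges and vessel wall in the number 2 pools would give, and spike-ins are added after tissue is taken, so both explanations may hold. For the number of gene lists called, 2 of the 3 splits gave as many (14 in the real one, highest of the others 14), too few for a share under 0.05. No biological explanation was tested, since the design gives none for the pool number.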

How the results depend on the processing

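No probe set passed an adjusted p of 0.05 in limma's test under any alternative run, nor 0.1, and 0 passed with the pool number as a replicate block, where 6054 had an unadjusted p under 0.05 against 4774 without. Differences between pool 1 and pool 2 correlated across probe sets with r = 0.33 between control and threat, but 2 pairs with no shared origin in the labels do not make a paired design. The rule of size gave 374 probe sets (50 higher, 324 lower), 5463 at 1.2-fold (2517 and 2946) and 48 at 2-fold (2 and 46). Median centring gave 79 higher. Without probe sets ending in _x_at or _s_at the rule gave 275 (46 and 229). Alternatives chosen after seeing the data gave 86 genes by the mean of their probe sets (6 and 80). They also gave 202 probe sets without the suffixes _a_at, _s_at and _x_at (161 lower), and 23 genes with at least 2 agreeing bright probe sets (1 and 22). Leaving out 1 pool, with the lone pool of an arm assumed to vary like the other group, gave 673 to 818 (higher 109 to 321, lower 352 to 709). Without 1 pool, the share of lower probe sets ran from 52.3% (without threat pool 1) to 86.7% (without threat pool 2), and was 53.9% at 1.2-fold. None of the 24 genes named by size passed the adjusted p under the alternatives run for them. Their direction without 1 pool was fixed by the rule that chose them, but the log2 difference moved by over 1.5 times for Acta2, Tpm2, Tagln, Myh11, Cytl1, Cryl1, Vegfd, Cbl and Ptprn2. Of the 120 leading list members, 17 turned direction without 1 pool and 74 moved by over 1.5 times or turned. Median centring moved the median of all probe sets by 0.036 and cyclic loess by -0.009.

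The 14 list calls became 0 with an estimated correlation (adjusted p 0.7025 or 0.7245 for each) and 0 with fry (0.6575 inflammatory; 0.67 glucocorticoid, myelin and choroid plexus; 0.7419 blood and heat shock; 0.7473 microglia; 0.7745 astrocyte and neurotrophin; 0.7933 clock; 0.83 antigen presentation; 0.8342 interferon and endothelial; 0.8655 mural). These 2 tests had little power with 2 residual degrees of freedom. With the replicate block the 14 calls were kept and the matrix list was added (0.0487). The clock list was lost with cyclic loess (0.104), bright probe sets (0.113), without the _x_at and _s_at suffixes (0.0534, as was antigen presentation) and with the mean of probe sets (0.0988). Lists gained a call with median centring (olfactory and matrix, 0.0485), bright probe sets (olfactory 0.0202, ribosomal 0.0176, matrix 0.0210), an intensity trend (ribosomal 0.0123, matrix 0.0491) and the mean of probe sets (olfactory, thalamic and glutamate receptor 0.0303, ribosomal 0.0363). Leaving out 1 pool gave 4 to 16 called lists. The adjusted p then ran for the called lists from 0.00105 to 0.195 (glucocorticoid), 5.98e-05 to 0.775 (clock), 6.11e-07 to 0.993 (interferon), 4.53e-07 to 0.993 (antigen presentation), 3.51e-07 to 0.158 (microglia), 2.75e-06 to 0.516 (astrocyte), 6.95e-08 to 0.301 (endothelial), 1.59e-07 to 0.827 (mural), 0.000329 to 0.0935 (blood), 0.000252 to 0.176 (neurotrophin) and 0.000302 to 0.358 (heat shock). For lists not called with all pools it ran from 3.71e-07 to 0.189 (immediate-early), 0.00932 to 0.993 (precursor), 0.00148 to 0.799 (striatal), 0.0115 to 0.437 (olfactory), 0.0307 to 0.797 (thalamic), 0.0282 to 0.688 (glutamate receptor), 0.0273 to 0.993 (synaptic), 0.0168 to 0.694 (ribosomal), 1.72e-05 to 0.308 (cell cycle) and 0.00104 to 0.993 (matrix). Among lists called with all pools, camera's direction turned for the clock list without control pool 1. It also turned for the mural list without control pool 2 or threat pool 1. Camera's direction need not follow a list's own median. Without 1 pool, the clock median stayed between 0.023 and 0.258. The interferon median ran from -0.24 to 0.048 while camera's direction was kept. For lists not called, camera's direction turned for the immediate-early, excitatory and oxidative phosphorylation lists without control pool 2 or threat pool 1. The same held for the striatal, synaptic and cell cycle lists without control pool 1. Camera's direction also turned for the stress signalling list without control pool 1 or threat pool 2, and for the matrix list without threat pool 1. The immediate-early median was 0.03 with all pools, against camera's direction, and ran from -0.216 to 0.365 without 1 pool. Under other alternatives camera's direction turned for the immediate-early, excitatory, oxidative phosphorylation, GABA and stress signalling lists, none of them called. The myelin, choroid plexus and inflammatory lists were called without each pool. Beyond the number of pools removed, the cause of these moves was not tested. Dim probe sets near the Bacillus controls limit what can be said of low transcripts. Without members at background in all pools, a count chosen after seeing the data, the median was -0.14 for the inflammatory list (28 genes), -0.12 interferon (30), -0.22 antigen presentation (19), -0.32 choroid plexus (16), -0.15 blood (10) and -0.17 neurotrophin (22).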

Other observations

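A rule chosen after the data were seen asked which genes were lower or higher in every 1 of at least 2 bright probe sets, with separate pools and a mean of at least 1.5-fold. Of 5401 genes with at least 2 bright probe sets, 22 were lower and 1 was higher in threat, and 12 of the 22 were on a fixed list, 7 of them on the myelin list. Among those on no fixed list were Tpm2 (2.48-fold lower over 2 probe sets, with 7.57 and 8.93 in the control pools), the elastic fibre protein Eln (1.79-fold), the myosin light chain kinase Mylk (1.77-fold) and the calcium pump regulator Pln (1.58-fold). The secreted protease Prss23 was 1.83-fold lower, Tmem123 1.80-fold, the chloride channel protein Clic4 1.68-fold over 3 probe sets, the growth inhibitor Btg1 1.65-fold, Vasn 1.57-fold, and Prr18 had a mean log2 difference of -0.59. Ankrd24 was 1.51-fold higher. Without control pool 2 the log2 difference was -0.63 for Tpm2, -0.50 for Eln, -0.39 for Pln and -0.43 for Vasn, and without threat pool 1 it was -0.32 for Clic4. The split by pool number gave 54 such genes, 5 higher and 49 lower in number 1, and the remaining split gave 0.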
